A study of Mus musculus with 4 samples.

How the data were processed

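Swiss 3T3 cells, a mouse fibroblast line, were profiled on 4 single-channel (Cy3) Agilent arrays of design 026655, whose probes are placed on mouse build mm9 per the file headers. Fibroblasts with intact Lpar1 (WT) and a single-cell CRISPR clone without it (KO) were each sampled at 0 h and 24 h of coculture with bone marrow-derived mast cells. The labels' protocols give 100 ng/ml SCF in the coculture, 200 ng of labelled RNA, and RNA pooled from 3 samples per array. The labels do not say what the 0 h samples held: the study's design text speaks of fibroblasts cocultured with or without mast cells. For separation after coculture the protocols name trypsin and reseeding, or beads against CD117, the Kit protein. All 4 arrays lay on 1 slide.

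The scanner files hold spot intensity, which per the file headers was extracted with Agilent Feature Extraction 12.1.1.1. Per the file headers, the processed intensity had its background removed by spatial detrending and was detrended within the array, but not scaled between arrays. The deposited value table holds a ratio: each value equals the array's processed signal divided by that array's 75th percentile as the file headers give it. Signal over table value was 1197.47, 1002.93, 926.641 and 749.899 on WT 0 h, KO 0 h, WT 24 h and KO 24 h, and constant within each array to the digits given. The table is therefore linear and not centred, and its direction is that of signal, so none of these stays unknown. Its column medians were 0.0442, 0.0483, 0.0452 and 0.0334 in the same order.

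Spots flagged as outliers and control spots were left out, the processed signal was taken to log2, and each array's 75th percentile over its 43020 non-control spots was subtracted. A normalized log2 signal of 0 is thus the array's own 75th percentile. Spots of a probe were averaged. Of 39429 probes, 29110 were named through their accession in the RefSeq gene table of GRCm38.p6, of which 344 changed symbol, and 10319 kept the file's name. No coordinates of that build are given. A gene took the value of its probe with the highest mean signal over the arrays, which gave 29658 genes. A gene counted as measured in a difference where its probe was well above background and not saturated on every array of that difference, and 17146 genes were measured on all 4.

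Each group has 1 array, so there is no spread between replicates, no test and no p-value. A gene is called higher or lower where it differed by at least 2-fold, which describes these arrays and not the conditions. Errors are standard errors (SE) from Feature Extraction's spot error, which is near 10 percent of a bright signal. The median SE was 0.20 on the log2 scale for a difference of 2 arrays and 0.29 for a difference of differences. It covers neither culture nor labelling. Where a gene was well above background on only 1 array of a pair, an at-least fold is given: the bright signal over the higher of the dim probe's own signal and the lowest signal among that array's probes well above background. Values near the floor have no order.

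Before the data were examined, 25 gene lists, the comparisons, the rule for named genes and the alternatives were fixed. The lists cover mast cell, pan-leukocyte, macrophage and granulocyte, and fibroblast markers; mast cell growth and maturation factors; prostanoid, lysophosphatidic acid, and hyaluronan and proteoglycan genes. They also cover collagen and matrix genes, matrix proteases and inhibitors, integrins and adhesion molecules, SRF and MRTF targets, YAP and TAZ targets, TGF-beta and BMP targets, and immediate early genes. The rest are inflammatory cytokines and chemokines, interferon-stimulated genes, cell cycle genes, p53 targets, cholesterol synthesis, fatty acid and adipogenic, hypoxia and glycolysis, unfolded protein and integrated stress response, NRF2 and metal response, and growth factors with IGF-binding proteins. All 508 entries are on the array, and 11 genes stand in more than 1 list.

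For each list the median difference of its measured genes was placed among 10000 random lists of the same size matched on mean signal. A list is said to stand apart where it lay in the lowest or highest 2.5 percent, which chance gives for 5 percent of lists of unrelated genes. Members of a list can vary together, so the 5 percent need not hold for these lists. Named genes are the 10 highest and 10 lowest of each difference that also passed 2-fold with normexp, the 4 largest at-least folds on each side, up to 3 members at each end of each list, and 17 genes of the study's pathway. For the difference of differences they are the 5 highest and 5 lowest. Fewer are named where space requires. Genes with provisional names (clones, predicted genes) were left out of the ranking.

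Alternatives fixed in advance were quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' value table, no filter on dim probes, a stricter filter (brighter than the median on average and well above background on all arrays), the mean of a gene's probes, and a difference over 2 SE. A further pair, chosen after seeing the data, scaled the arrays on fibroblast and collagen genes and left out genes lower at 24 h in both genotypes. On lists, 5 settings can move a result: quantile normalization, normexp, no filter, the stricter filter and the mean of probes. The authors' table and fibroblast scaling shift all genes of a difference alike up to rounding, and the 2 SE rule and leaving out genes were run on counts alone. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.

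The counting rule and the list percentiles were tested on simulated data. These covered the 19207 genes measured on both WT arrays. Of 50 genes raised and 50 lowered 2.83-fold, 49 and 47 were called, and all 50 of each at 8-fold. Of 19007 unchanged genes 16 were called. The simulation did not keep the real WT differences between 24 h and 0 h, of which 3028 were called higher and 1070 lower. The simulation left out any offset of dim spots. On the real arrays the 2 spike-in RNAs with a mean signal below −4 read 1.11 higher on WT 24 h than on WT 0 h. Of 200 simulated lists of 20 unchanged genes 11 stood apart (5.50 percent). Of 200 lists shifted by 0.3 on the log2 scale 199 did (99.5 percent). These simulated counts and percentages describe the simulated data alone. They do not give the error rates of the real arrays or of the real lists.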

Results

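The arrays compared the transcripts of Lpar1+/+ (WT) and Lpar1-/- (KO) Swiss 3T3 fibroblasts at 0 h and 24 h of coculture with mast cells, with 1 array of pooled RNA per group and no replicates. Lpar1 encodes a receptor for lysophosphatidic acid, a signalling lipid. The labels and title place the series in a study of how fibroblasts and mast cells act on each other as mast cells mature. The comparisons ask which fibroblast genes differ between the times in each genotype, and which differ between genotypes at each time. Spots well above background made up 72.7% (WT 0 h), 71.5% (KO 0 h), 67.3% (WT 24 h) and 62.1% (KO 24 h) of the non-control spots, and no spot was saturated. Probes printed 10 times had a median SD of 0.073, 0.076, 0.084 and 0.11 log2 on these arrays. The number of arrays limits the precision of every value.

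The arrays labelled 0 h carried abundant mast cell transcripts and those labelled 24 h carried little of them. Of 23 mast cell markers, 22 were well above background on each 0 h array and 14 on each 24 h array. Their median signal was 2.88 on WT 0 h and 3.96 on KO 0 h, against −5.50 on WT 24 h and −5.40 on KO 24 h. Cpa3, a mast cell protease, read 6.19, 6.25, −1.75 and −1.07 on WT 0 h, KO 0 h, WT 24 h and KO 24 h, and Fcer1a, a chain of the IgE receptor, read 5.48, 5.59, −3.51 and −2.82. The 20 pan-leukocyte markers followed the same order, with medians of 2.26, 3.24, −4.60 and −4.56. The 21 fibroblast markers had medians of 1.13, 0.18, 1.99 and 1.31. All differences between times below are therefore differences between arrays as labelled, taken in the presence of this one.

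**Figure D1:**
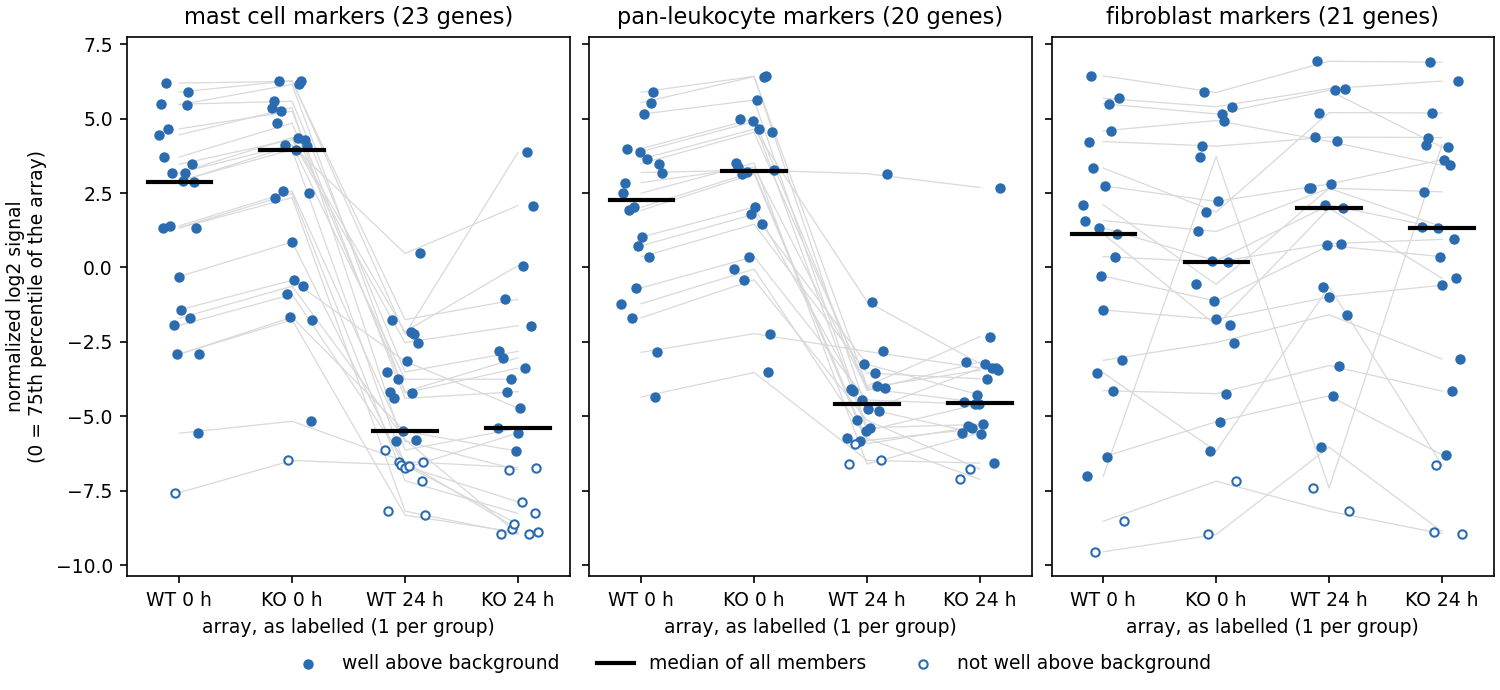
Normalized log2 signal (y axis, 0 is each array's 75th percentile) of mast cell, pan-leukocyte and fibroblast markers on the 4 arrays (x axis, 1 array per group). Points are genes joined by lines, hollow where not well above background, and bars are medians over all members. Mast cell medians are 2.88 and 3.96 on the 0 h arrays and −5.50 and −5.40 on the 24 h arrays.

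Lpar1 itself gave nearly the same signal on all arrays. Its only probe, on chromosome 4 from 58499672 to 58499731 (mm9), read −3.20 on WT 0 h, −3.43 on KO 0 h, −3.15 on WT 24 h and −3.61 on KO 24 h. KO minus WT was −0.22 at 0 h and −0.46 at 24 h, each with an SE of 0.21. The labels place the guide next to exon 3, and the probe's place relative to the edit was not analysed here, so this probe checks nothing about the genotype.

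Of the study's own genes, Il33, Enpp2 and Kitl each differed by at least 2-fold in several comparisons. Il33, an alarmin that activates mast cells (probe on chromosome 19 from 30035101 to 30035160, mm9), was higher at 24 h by 3.37 log2 in WT and 3.10 in KO. It was lower in KO by −2.91 at 0 h and −3.18 at 24 h. Enpp2, which encodes autotaxin, the enzyme that makes lysophosphatidic acid (chromosome 15 from 54670921 to 54670980, mm9), was higher at 24 h by 4.26 in WT and 2.80 in KO. KO minus WT for Enpp2 was 2.33 at 0 h and 0.87 at 24 h. Kitl, which encodes SCF, the growth factor of mast cells (chromosome 10 from 99558962 to 99559021, mm9), was lower in KO by −2.06 at 0 h and −1.24 at 24 h. Its 24 h minus 0 h difference was 0.45 in WT and 1.27 in KO. Each of these differences has an SE of 0.20 to 0.21.

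Tslp, another cytokine that acts on mast cells, was higher in KO by 1.1 at 0 h and 1.16 at 24 h. Has2, a hyaluronan synthase, had KO minus WT differences of −0.76 and −1.47. Cd44, the hyaluronan receptor, differed by 0.17 and 1.36 at its brightest probe, and its 4 probes spanned 0.84 to 1.36 at 24 h. The cyclooxygenase Ptgs2 was 2.26 higher in KO at 24 h and 0.87 at 0 h, and its 24 h minus 0 h difference was −2.11 in WT and −0.71 in KO. Ptgs1, the other cyclooxygenase, differed between genotypes by −0.079 at 0 h and 1.12 at 24 h. Ptgds, the lipocalin-type prostaglandin D synthase, was not well above background on either KO array and was at least 2.5-fold higher on WT 24 h than on KO 24 h and at least 1.42-fold at 0 h. Its brightest reading, −5.24, lay close to the floor.

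Among the other lysophosphatidic acid receptors, Lpar4 was lower in KO by −1.57 and −2.45. Lpar6 was lower at 24 h by −2.67 in WT and −4.14 in KO, in the same direction as the mast cell markers. Lpar2 differed by −0.84 and 0.19 between genotypes at its brighter probe, and its 2 probes disagreed in sign (0.55 and −0.91 at the dimmer). Lpar5 was dim on all arrays (−6.02, −5.31, −5.56 and −6.04 on WT 0 h, KO 0 h, WT 24 h and KO 24 h). Lpar3 was not well above background on any array, and neither Has1 nor Has3 was so on all 4.

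In WT cells, the median difference between 24 h and 0 h stood below random lists for mast cell, leukocyte and immediate early genes, and above them for interferon-stimulated, cholesterol synthesis and fibroblast genes. All 14 measured mast cell markers were lower, with a median of −7.08, and 6 more had at-least folds in that direction. Of 17 measured leukocyte markers 15 were lower, with a median of −5.77. The lowest genes measured on both WT arrays were Csf2rb2 (−10.71), a receptor subunit for IL-3, Tph1 (−10.64), which makes serotonin, and Alox5 (−10.54), which makes leukotrienes. Rab44 (−10.21), Gzmb (−10.05), Srgn (−9.68), Adora3 (−9.68), Csf2rb (−9.52), Rac2 (−9.37) and Lilrb4a (−9.25) followed. Second probes of Csf2rb and Lilrb4a gave −7.18 and −7.03. Scin, Kit, Rprm and Rgs1 were well above background at 0 h only, at least 2056-fold, 1545-fold, 1305-fold and 852-fold higher there.

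The highest genes on WT 24 h, of those measured on both arrays, were Lrrc17 (4.40), Enpp2 (4.26), Hp (4.16), which encodes the acute-phase protein haptoglobin, Gdpd2 (3.95) and Serpina3n (3.90), an acute-phase protease inhibitor. Cyp2f2 (3.83), Pf4 (3.72), Spib (3.62), Ppp1r3c (3.58) and Batf3 (3.57) completed them. Lrrc17, Serpina3n, Ppp1r3c and Batf3 read below −5 on WT 0 h, where small signals carry the largest error. With normexp their differences were 2.02, 2.29, 1.37 and 1.52, and Cyp2f2 (3.62) and Enpp2 (3.40) were the highest of these genes. SEs of these 20 ranged from 0.20 to 0.32. In all, 3028 genes were at least 2-fold higher and 1070 lower of 19207 measured, around a median of 0.28. Of the higher calls 2427 lay below a mean signal of −4, where the 2 dim spike-in RNAs read 1.11 higher, and at or above −4 there were 601 higher and 906 lower. Higher calls made up 73.9% of calls, against 64.8% with quantile normalization (2119 higher, 1149 lower), 38.6% with normexp (461 and 732) and 46.9% with the stricter filter (249 and 282).

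Of the 25 lists, 13 stood apart in WT, and 8 did so in all 5 settings that can move a list. Interferon-stimulated genes had 13 of 23 measured members higher and 0 lower, with a median of 1.1, led by Ifit3 (2.57), Irf7 (2.02, dim) and Gbp2 (1.71). Cholesterol synthesis genes had 11 of 19 higher and 0 lower (median 1.04), led by Dhcr7 (1.83), Mvd (1.58) and Fdft1 (1.57). Fatty acid and adipogenic genes had 6 of 14 higher and 0 lower (median 0.92), among them Pparg (1.52), the master regulator of fat cell formation. Fibroblast markers had 6 of 18 higher and 0 lower (median 0.66), among them Fap (2.88) and Dcn (1.86), a matrix proteoglycan. They moved against the mast cell markers, whose median was −7.08. Across all settings, fibroblast scaling included, the lowest medians were 0.64 (interferon-stimulated), 0.58 (cholesterol), 0.47 (fatty acid) and 0.21 (fibroblast). The part of the mast cell signal of the 0 h arrays in these higher medians was not tested.

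Immediate early genes had 14 of 20 lower and 0 higher in WT (median −2.02), led by Fosb (−5.57), Egr2 (−3.22) and Fos (−3.17), and moved with the mast cell markers. TGF-beta and BMP targets had a median of −0.26, with 2 of 17 lower, among them Id2 (−2.74), and Tgfbi (2.14) higher. The other lists that stood apart did so only under some settings. Prostanoid genes (median 0.52, 6 higher and 3 lower of 23) included Ptger1 (2.36) and Pla2g2e (2.28), and Tbxas1 (−7.14) and Hpgds (−4.07) at the other end. Their median was 0.18 with normexp and 0.29 with the stricter filter, inside the random range. Matrix proteases and inhibitors (0.53, 6 higher and 3 lower of 20) turned to −0.24 with the stricter filter, below the random range, and did not stand apart at 0.33 with the mean of probes or 0.29 with no filter. YAP and TAZ targets (−0.093, 0 higher and 2 lower of 14) had 0.0063 with no filter.

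NRF2 and metal response genes (−0.097, 1 higher and 2 lower of 16) and growth factors (0.59, 6 higher and 3 lower of 21) lost their place as well in WT. The first did so with quantile normalization (−0.10) and normexp (−0.11), the second with no filter (0.40) and the stricter filter (0.12). The remaining WT medians lay inside the random range: macrophage and granulocyte markers 0.29, mast cell growth factors 0.14, lysophosphatidic acid genes 0.43, hyaluronan genes 0.43, collagen and matrix genes 0.35, and integrins 0.35. SRF targets had 0.21, inflammatory genes 0.43, cell cycle genes 0.097 with 0 of 23 members 2-fold apart, p53 targets 0.19, hypoxia genes 0.24 and stress response genes 0.34.

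In KO cells, the median difference again stood below random lists for mast cell, leukocyte and immediate early genes, and above them for fibroblast, integrin, lipid synthesis and growth factor genes. All 14 measured mast cell markers were lower (median −6.87), with at-least folds in that direction for 8 more, and 17 of 18 leukocyte markers were lower (median −7.95). The lowest genes measured on both KO arrays were Scin (−11.34), Rab44 (−11.18), Adora3 (−10.91), Alox5 (−10.89), Rprm (−10.82) and Kit (−10.77), the SCF receptor. Atp8b5 (−10.47), Gzmb (−10.25), Cst7 (−10.02) and Tph1 (−9.89) came next, though the 3 probes of Atp8b5 ranged from −10.47 to 0.66. Igfbp5, Cx3cr1, Cd69 and Rgs1 were at least 2231-fold, 2027-fold, 1746-fold and 1717-fold higher on KO 0 h.

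The highest genes on KO 24 h, of those measured on both arrays, were Arhgap8 (4.06), Ubd (3.93), a ubiquitin-like protein, C3 (3.58), the central complement component, and Ptgfr (3.37), the prostaglandin F receptor. Dcn (3.33), Zbp1 (3.32), Ccl8 (3.28), a chemokine, Urah (3.18), Il33 (3.10) and Osmr (3.00), the oncostatin M receptor, completed them. The 2 probes of Zbp1 differed, at 0.40 and 3.32. Spib was at least 20.7-fold and Wt1 at least 12.4-fold higher on KO 24 h than on KO 0 h. SEs of the 20 ranged from 0.20 to 0.33. Arhgap8, Ubd and Urah read below −5 on KO 0 h, and with normexp their differences were 2.66, 2.04 and 1.87. In all, 1694 genes were higher and 1952 lower of 17879, around a median of 0.23. At or above a mean signal of −4 there were 1453 higher and 1357 lower, and the 8 spike-ins in that range read 0.48 higher. Below it there were 241 and 595, where dim spike-ins read −0.27. Higher calls were 46.5% of calls, against 60.8% with quantile normalization (2274 and 1468) and 62.5% with the stricter filter (793 and 476). With normexp 996 were higher and 1191 lower.

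Of the 25 lists, 14 stood apart in KO and 10 did so in all 5 settings that can move a list. Fibroblast markers had 9 of 18 higher and 3 lower (median 0.94), with Dcn (3.33), Pdgfra (1.94) and Fbln1 (1.58) at one end and Cd34 (−1.5) and Ly6a (−1.12) at the other. Lysophosphatidic acid genes had 6 of 16 higher and 1 lower (median 0.78), led by Enpp2 (2.80), S1pr1 (1.55) and Plpp2 (1.19). Integrins and adhesion molecules had 3 of 14 higher and 0 lower (median 0.78), led by Vcam1 (1.45), Itga6 (1.16) and Itgb5 (1.14), although the mean of the Itga6 probes was −0.048. By at-least folds 1 more member was higher and 2 lower, which gave a median of 0.70. Cholesterol synthesis genes (8 of 19 higher, 0 lower, 1 more lower by an at-least fold, median 0.69) were led by Mvd (2.17) and Nsdhl (2.06), and fatty acid genes (5 of 14 higher, 1 lower, median 0.84) by Dgat2, Fabp4 and Pparg (1.33 each). Across all settings, fibroblast scaling included, the lowest medians were 0.43 (fibroblast), 0.27 (lysophosphatidic acid), 0.27 (integrin), 0.18 (cholesterol) and 0.33 (fatty acid). The part of the mast cell signal of the 0 h arrays in these higher medians was not tested.

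Growth factors had 9 of 21 higher and 1 lower in KO, with 1 more lower by an at-least fold (median 0.68), led by Fgf10 (2.53) and Hgf (2.02). Immediate early genes had 15 of 19 lower and 0 higher (median −2.43), led by Fosb (−6.93), Fos (−5.23) and Egr2 (−3.88). Hypoxia and glycolysis genes had 5 of 18 lower and 0 higher (median −0.45), led by Car9 (−5.35) and Bnip3 (−2.88). Both moved with the mast cell markers (median −6.87) and leukocyte markers (−7.95). Some lists stood apart only under some settings. Hyaluronan genes (0.62, 5 of 14 higher, 0 lower) did not with quantile normalization (0.44), normexp (0.34), no filter (0.098) or the mean of probes (0.51).

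In KO, matrix proteases (0.89, 9 of 21 higher, 0 lower) did not stand apart with the stricter filter (0.60), nor inflammatory genes (0.85, 6 higher and 3 lower of 15, and 2 more lower by at-least folds) with no filter (0.33), nor cell cycle genes (0.64, 3 of 23 higher, 0 lower) with the mean of probes (0.59). Inside the random range were macrophage and granulocyte markers at 0.035, mast cell growth factors at 0.51, prostanoid genes at 0.55, collagen genes at 0.28, SRF targets at 0.38 and YAP targets at 0.39. TGF-beta targets (0.48), interferon-stimulated genes (0.45), p53 targets (0.062), stress response genes (0.25) and NRF2 genes (0.060) were inside it too.

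**Figure D2:**
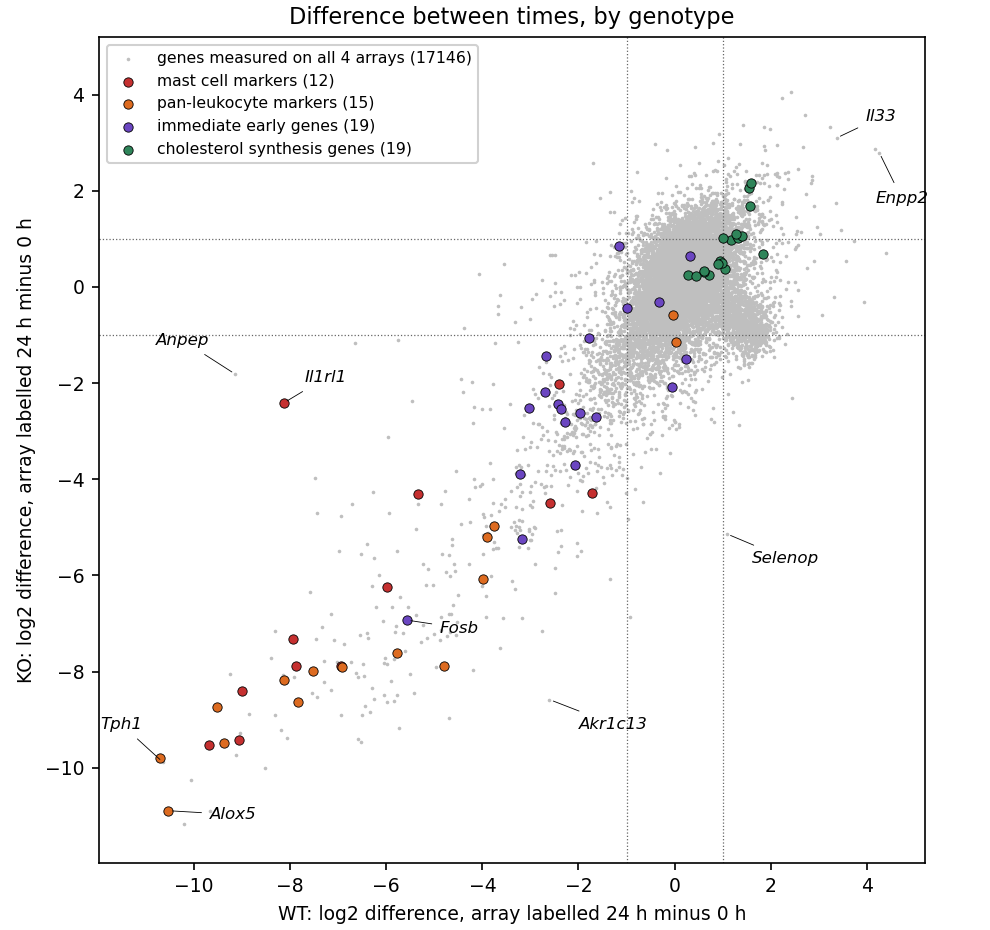
Log2 difference between the arrays labelled 24 h and 0 h in WT (x axis) and KO (y axis) for 17146 genes measured on all 4 arrays, with 4 lists in colour and dotted lines at 2-fold. Mast cell and most leukocyte markers lie low in both genotypes, while Il1rl1, Anpep, Selenop and Akr1c13 lie off the diagonal.

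The differences between times were related across genes in WT and KO, with a Pearson r of 0.67 and a Spearman rho of 0.33 over 17146 genes, which are not independent replicates. At least 2-fold lower in both were 760 genes, against 101.4 for independent lists, and higher in both 354, against 160.2. In opposite directions were 253. The pair of differences shares no array. The Pearson r ranged from 0.55 with no filter to 0.80 with normexp. The mast cell markers were lower in both genotypes (medians −7.08 in WT and −6.87 in KO). The relation therefore includes the mast cell signal of the 0 h arrays, and how much of it remains without that signal was not tested.

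The KO and WT changes differed over 16-fold in single genes. Of genes measured on all 4 arrays, the KO change exceeded the WT change most in Anpep (7.32), which encodes aminopeptidase N, Il1rl1 (5.72), the IL-33 receptor, Asphd2 (5.48), Prelid2 (4.65) and Sprr2d (4.26). It fell short most in Selenop (−6.22), a selenium carrier, Akr1c13 (−5.98), Arhgap20 (−5.93), Nat8 (−4.75) and Gngt2 (−4.73). SEs of these 10 ranged from 0.29 to 0.39, and none of the differences has a replicate. Nat8 read −6.50 on KO 24 h, close to the floor, and its difference was −2.34 with normexp. Il1rl1 had a 24 h minus 0 h difference of −2.41 in KO and −8.14 in WT, while the mast cell markers as a list had medians of −6.87 and −7.08. Of 17146 genes, 804 had a KO change at least 2-fold above the WT change and 2279 at least 2-fold below. Of the latter 1446 had a mean signal below −4, where dim spike-ins differed by −1.39, and at or above it 695 lay above and 833 below. These were 1261 and 1510 with quantile normalization, 467 and 661 with normexp, and 322 and 281 with the stricter filter.

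As a group, TGF-beta and BMP targets had KO changes above WT changes (median difference 0.81, 4 of 17 at least 2-fold, 0 below), as did YAP and TAZ targets (0.62, 4 of 14, 0 below), matrix proteases (0.69, 8 of 20, 0 below) and cell cycle genes (0.57, 4 of 23, 0 below). Growth factors (0.81, 6 above and 2 below of 18) and fibroblast markers (0.33, 3 above and 4 below of 17) stood above as well. Below were interferon-stimulated genes (−0.51, 7 of 21, 0 above), hypoxia genes (−0.68, 5 of 17, 0 above), cholesterol synthesis genes (−0.28, 1 of 19) and stress response genes (−0.19, 5 of 19). These 10 lists stood apart in all 5 settings that can move a list. None of these settings removes mast cell RNA. KO 0 h carried more mast cell signal than WT 0 h (median difference 1.03), and its part in these values was not tested. Cholesterol synthesis genes had KO minus WT medians of 0.38 at 0 h and −0.011 at 24 h, while TGF-beta targets had 0.49 and 1.20.

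The difference of changes in leukocyte markers (−0.79), hyaluronan genes (0.60), immediate early genes (−0.17) and inflammatory genes (0.46) stood apart only under some settings. Leukocyte markers had −0.24 with the stricter filter, and hyaluronan and inflammatory genes had −0.092 and 0.019 with no filter. Immediate early genes were inside the random range with normexp (−0.16), the stricter filter (−0.094) and the mean of probes (−0.17). The mast cell markers (0.074) lay inside the random range.

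At 0 h, the median KO minus WT difference stood above random lists for SRF targets, TGF-beta targets and mast cell markers, and below them for collagen genes and fibroblast markers. Of genes measured on both 0 h arrays, the highest in KO were Thy1 (10.74), a surface glycoprotein of many fibroblasts, Actg2 (8.02) and Tagln (8.02), smooth muscle cytoskeletal genes, Lysmd2 (6.76), Emp2 (6.24) and Ror2 (5.93), a Wnt receptor. Tspan18 (5.48), Sprr2e (5.18), Chst10 (5.11) and Diras2 (5.09) completed them. The lowest of the same genes were Syt13 (−8.99), Pcolce2 (−5.72), Fbxl7 (−5.62), Lpl (−5.41), which encodes lipoprotein lipase, Lifr (−5.20) and Ch25h (−5.17). Gprin3 (−5.15), Ecscr (−5.14), Chst8 (−5.02) and Rspo3 (−4.86), a Wnt agonist, completed them. The 3 probes of Lifr ranged from −5.20 to −2.18 and the 2 of Tspan18 from 3.16 to 5.48. SEs of these 20 ranged from 0.20 to 0.34. Thy1, Lysmd2, Ror2, Tspan18, Sprr2e and Chst10 read below −5 on WT 0 h. So did Syt13, Fbxl7, Ch25h, Gprin3, Chst8 and Rspo3 on KO 0 h, so the size of these differences is uncertain. With normexp Ror2 was 3.44, Gprin3 −2.63, Chst8 −2.67 and Rspo3 −2.57, while Tagln was 7.98.

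Tpd52l1, Scrn1, Meg3 and Foxa2 were well above background on KO 0 h and not on WT 0 h, at least 308-fold, 226-fold, 143-fold and 101-fold higher. F11r, Xist, Wt1 and Avpr1a were the reverse, at least 282-fold, 223-fold, 122-fold and 81.9-fold higher in WT. Of 20313 genes 1882 were higher and 822 lower in KO. Below a mean signal of −4, where dim spike-ins read 0.64 higher in KO, there were 1045 higher and 139 lower, and at or above it 837 and 683. Higher calls were 69.6% of calls, against 58.1% with quantile normalization (1379 and 995), 59.3% with normexp (800 and 548) and 39.1% with the stricter filter (185 and 288). Leaving out genes lower at 24 h in both genotypes, mast cell genes among them, left 18778 genes, with 1130 higher and 817 lower. More genes were left out than the 760 lower in both among those measured on all 4 arrays. The choice used KO 0 h signal, so part of the fall in higher calls follows by construction.

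Of the 25 lists, 13 stood apart at 0 h and 9 did so in all 5 settings that can move a list. Mast cell markers were higher in KO (median 1.03, 13 of 22 at least 2-fold, 0 lower), as were leukocyte markers (1.01, 13 of 20, 0 lower). SRF and MRTF targets, the contractile cytoskeleton genes, had 8 of 17 higher and 0 lower (median 0.88), led by Actg2 (8.02), Tagln (8.02) and Myl9 (4.77). TGF-beta and BMP targets had 4 of 17 higher and 1 lower (median 0.49), among them Grem1 (3.82), a secreted BMP antagonist, and Cdkn2b (2.07). Collagen and matrix genes had 6 of 25 lower and 4 higher (median −0.47), with Col6a2 (−2.08), Col6a1 (−1.80) and Loxl1 (−1.80) lower and Fbln5 (3.72), Postn (2.71) and Tnc (2.66) higher. Fibroblast markers had 5 of 19 lower and 2 higher (median −0.34), with Fbln1 (−3.07), Pdgfra (−2.67) and Fap (−2.64) lower. KO 0 h carried more mast cell signal than WT 0 h, and its part in the lower collagen and fibroblast medians was not tested. At 24 h, where mast cell signal was low, the collagen median was −0.20, inside the random range. The fibroblast median was then −0.38 and stood apart under some settings only.

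Immediate early genes, which were higher on both arrays rich in mast cell signal, had 3 of 20 higher and 0 lower in KO at 0 h (median 0.72), led by Dusp5 (1.20). Cholesterol synthesis genes (0.38) and hypoxia genes (0.25) stood above with 0 members 2-fold higher, and Adm (−2.66) was the 1 hypoxia gene lower. Lysophosphatidic acid genes (−0.31, 3 higher and 3 lower of 16) were inside the random range with no filter (−0.064), the stricter filter (−0.15) and the mean of probes (−0.18). Fatty acid genes (0.59, 3 higher and 1 lower of 16) had 0.23 with quantile normalization, 0.067 with normexp and −0.17 with the stricter filter, all inside it. Growth factors (−0.30, 7 higher and 5 lower of 20) were inside it with quantile normalization (−0.27) and the stricter filter (−0.36), and stress response genes (0.082, 0 of 19 2-fold apart) with the mean of probes (0.030).

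The other lists at 0 h lay inside the random range. Their medians were 0.25 for macrophage and granulocyte markers, −0.080 for mast cell growth factors, −0.10 for prostanoid genes, −0.14 for hyaluronan genes, −0.14 for matrix proteases and 0.34 for integrins. YAP targets had −0.20, inflammatory genes −0.22, interferon-stimulated genes −0.0014, cell cycle genes −0.26, p53 targets 0.13 and NRF2 genes −0.29.

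At 24 h, where mast cell signal was low on both arrays, the median KO minus WT difference stood above random lists for SRF targets, TGF-beta targets and matrix proteases and below them for interferon-stimulated and hypoxia genes. Of genes measured on both 24 h arrays, the highest in KO were Tagln (9.79), Dynap (7.78), Ramp3 (7.51), Anpep (7.16), Sprr2d (7.06), Emp2 (7.05) and Asphd2 (6.84). Tgm2 (6.6), the tissue transglutaminase, Timp3 (6.27), an inhibitor of matrix proteases, and Osr1 (6.25), a transcription factor of mesenchyme, completed them. The second probe of Tgm2 gave 5.40. The lowest of the same genes were Syt13 (−9.04), Ggt6 (−7.28), Selenop (−6.49), Fgl1 (−6.35), Lpl (−6.13), Fbxl7 (−5.58), Rhbdl3 (−5.44), Rasgrp2 (−5.38), Gdpd2 (−5.34) and Akr1c13 (−5.29). SEs of these 20 ranged from 0.20 to 0.33. Dynap, Anpep, Sprr2d, Asphd2 and Osr1 read below −5 on WT 24 h, and Ggt6, Fgl1, Rhbdl3 and Gdpd2 on KO 24 h. The size of these differences is therefore uncertain. With normexp Osr1 was 4.35, Fgl1 −4.03 and Rhbdl3 −2.94, while Tagln was 8.77.

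Thy1, Actg2, Scrn1 and Tpd52l1 were well above background on KO 24 h and not on WT 24 h, at least 1246-fold, 581-fold, 324-fold and 227-fold higher. Cyp2f2, F11r, Avpr1a and Grpr were the reverse, at least 690-fold, 441-fold, 238-fold and 231-fold higher in WT. Of 17313 genes 998 were higher and 2122 lower in KO. Higher calls were 32.0% of calls, against 46.2% with quantile normalization (1200 and 1396), 50.3% with normexp (678 and 669) and 53.4% with the stricter filter (354 and 309). Most lower calls were of dim genes: 1216 lay below a mean signal of −4, where dim spike-ins read −0.75, and 906 at or above it, where 869 were higher.

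**Figure D3:**
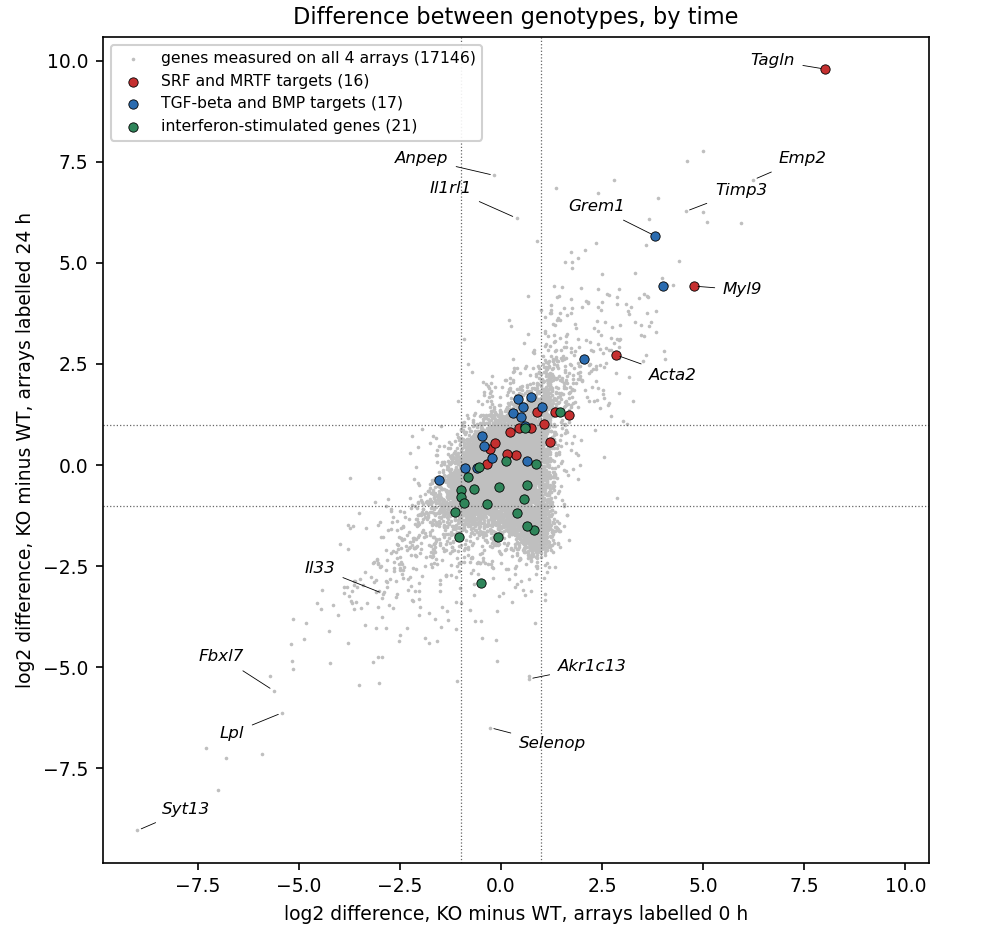
Log2 difference between KO and WT on the arrays labelled 0 h (x axis) and 24 h (y axis) for 17146 genes measured on all 4 arrays, with 3 lists in colour and dotted lines at 2-fold. Tagln lies at 8.02 and 9.79, and Syt13 at −8.99 and −9.04.

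Of the 25 lists, 14 stood apart at 24 h and 8 did so in all 5 settings that can move a list. TGF-beta and BMP targets had 9 of 17 higher in KO and 0 lower (median 1.20), among them Grem1 (5.66) and Cdkn2b (2.63). SRF and MRTF targets had 7 of 16 higher and 0 lower (median 0.92), led by Tagln (9.79), Myl9 (4.43) and Acta2 (2.72), which encodes smooth muscle actin. Matrix proteases and inhibitors had 9 of 20 higher and 2 lower (median 0.69), led by Timp3 (6.27), Serpinb2 (4.35) and Plau (3.12), with Adamts1 at −2.45. Integrins and adhesion molecules had 3 of 13 higher and 1 lower (median 0.70), led by Alcam (1.70) and Itgb1 (1.16). By at-least folds 2 more were higher and 3 lower, so 5 stood higher and 4 lower, with a median of 0.66. Interferon-stimulated genes had 7 of 21 lower and 1 higher (median −0.79), led by Usp18 (−2.92), Ifit3 (−1.79) and Isg15 (−1.77), with 1 more higher and 2 more lower by at-least folds. Hypoxia genes had 5 of 17 lower and 1 higher (median −0.45), led by Adm (−3.53) and Pdk1 (−2.87).

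Immediate early genes (0.38, 4 higher and 2 lower of 19) included Dusp5 (2.43) and Fosl1 (2.40) above and Btg2 (−2.43) and Fos (−1.32) below at 24 h, with 1 more lower by an at-least fold. Cell cycle genes had a median of 0.29, with Ccnb2 (1.56) the 1 gene of 23 at least 2-fold apart. The rest that stood apart did so under some settings only. Mast cell growth factors (−0.43, 2 higher and 4 lower of 11), with Il33 (−3.18), Il6 (−2.21) and Kitl (−1.24) lower and Csf2 (1.27) and Tslp (1.16) higher, were inside the random range with no filter, at the same median. Inflammatory genes (−0.36, 3 higher and 7 lower of 16), with Cxcl5 (−3.56), Lcn2 (−3.37) and C3 (−3.03) lower and Il11 (2.35) higher, were inside it with the stricter filter (−0.29).

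Fibroblast markers at 24 h (−0.38, 5 of 17 lower, 0 higher, 1 more each way by at-least folds), with Fbln1 (−2.36) and Ly6a (−1.91) lower, were inside the random range with normexp (−0.22) and the stricter filter (−0.12). YAP targets (0.37, 4 of 14 higher, 0 lower), led by Ccn2 (3.56), were inside it with the mean of probes (0.33). The p53 targets (−0.42, 1 higher and 4 lower of 16) were inside it with normexp (−0.24) and the mean of probes (−0.27). Mast cell markers (0.69, 4 higher and 1 lower of 12) were led by Il1rl1 (6.11), Gata2 (2.22) and Rab27b (1.61), and had 0.0031 with no filter.

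The remaining lists at 24 h were inside the random range. Their medians were −0.15 for leukocyte markers, 0.055 for macrophage and granulocyte markers, −0.010 for prostanoid genes, −0.11 for lysophosphatidic acid genes, −0.13 for hyaluronan genes and −0.20 for collagen genes. Cholesterol synthesis genes had −0.011, fatty acid genes −0.046, stress response genes −0.19, NRF2 genes 0.038 and growth factors −0.079. Pla2g3, the secreted phospholipase of the lysophosphatidic acid list, differed by 1.06 at 0 h and −1.47 at 24 h, but was dim on all arrays, between −6.41 and −4.83.

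**Figure D4:**
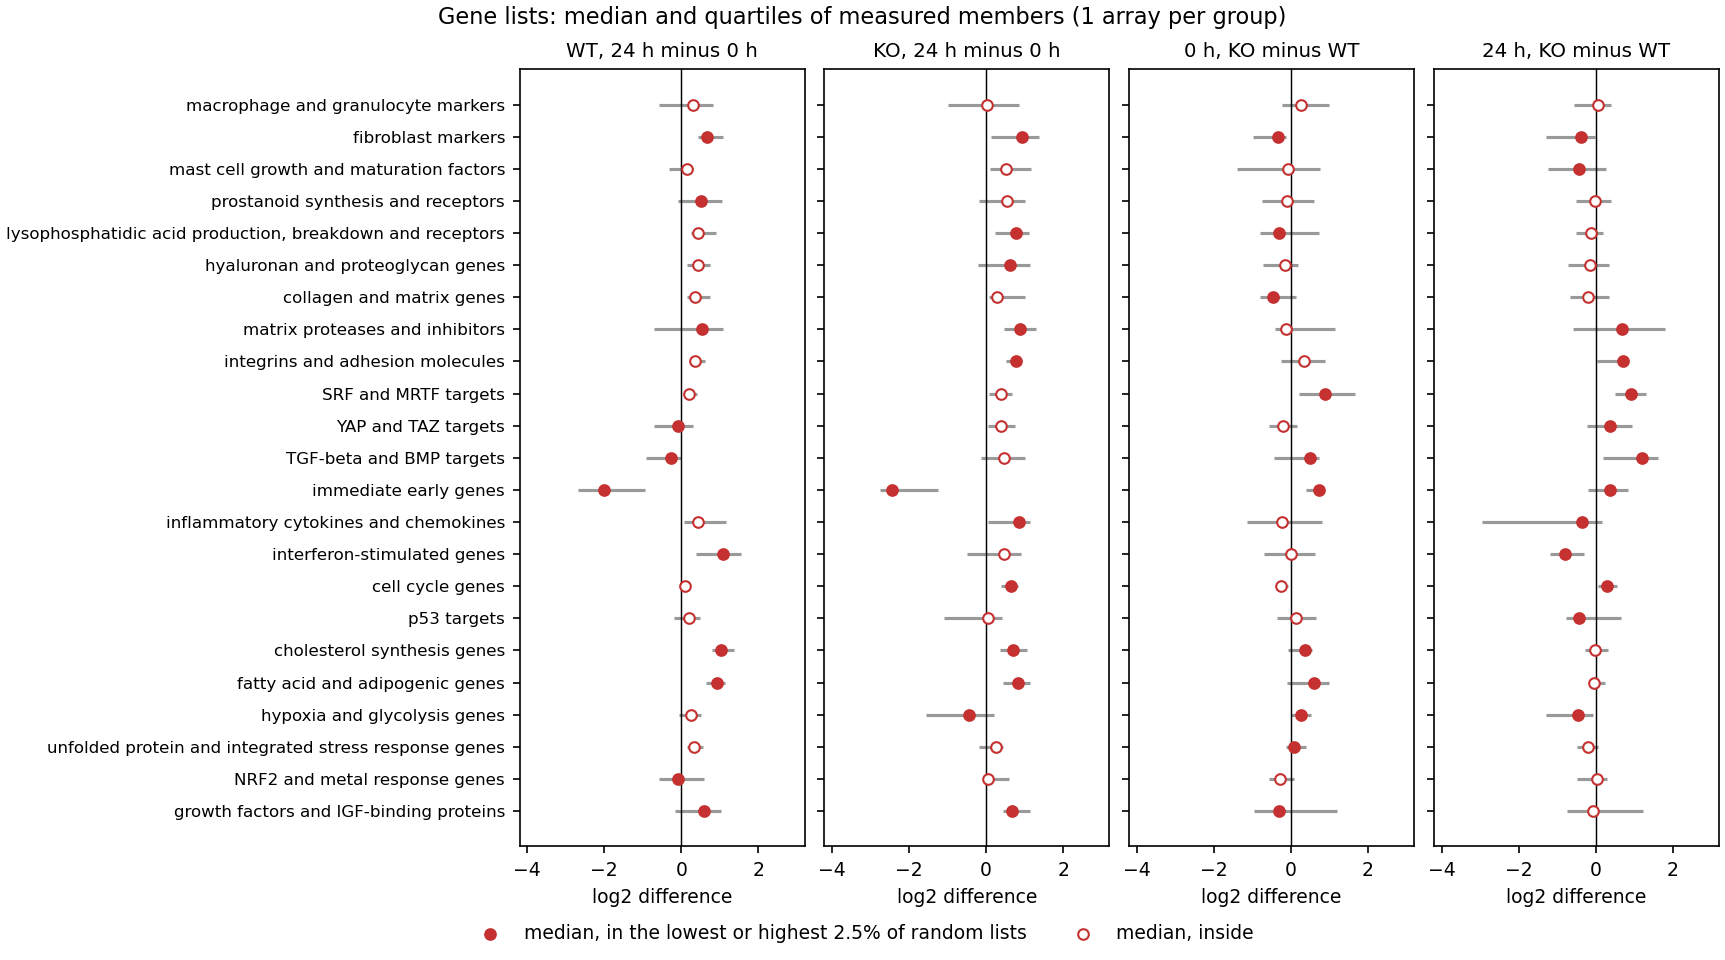
Median log2 difference (points) and quartiles (lines) of the measured members of 23 gene lists for the 4 differences, with filled points where the median lay in the lowest or highest 2.5% of 10000 random lists. The mast cell and leukocyte lists, with medians to −7.95, are not drawn. SRF and TGF-beta targets lie above 0 in both KO minus WT panels.

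The genotype differences at the 2 times were related across genes, with a Pearson r of 0.42 and a Spearman rho of 0.20 over 17146 genes, and they share no array. Higher in KO at both times were 433 genes, against 55.7 for independent lists, lower at both 403, against 94.7, and in opposite directions 217. The Pearson r ranged from 0.21 with no filter to 0.59 with normexp. At least 8-fold apart in the same direction at both times were 80 genes, 37 higher and 43 lower in KO, and none was 8-fold apart in opposite directions.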

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

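Every test of an explanation in this part was chosen after the result was seen. Among the genes named by the rule fixed in advance, 13 stood at least 2-fold apart in opposite directions in the 2 groups of a contrast. Over all genes there were 253 such genes for the times and 217 for the genotypes. With 1 array per group the difference between the groups was not tested.

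Between the arrays labelled 24 h and 0 h, the WT and KO differences went opposite ways in Nat8 (2.44 in WT, −2.32 in KO), Pdk1 (1.40, −1.98), Ramp3 (−1.35, 1.56), Selenop (1.08, −5.13), Sprr2d (−1.69, 2.57) and Tcf21 (2.06, −1.11). Between KO and WT, the arrays labelled 0 h and 24 h went opposite ways in Alox5ap (1.01 at 0 h, −2.08 at 24 h), Cd53 (1.06, −1.03), Cemip (1.21, −1.01), Fgf2 (1.02, −1.30), Hdc (1.00, −1.57), Igfbp2 (1.43, −1.43), Pla2g3 (1.06, −1.47) and Tcf21 (1.18, −1.98). Of these 13 genes, Cemip, Fgf2, Igfbp2, Nat8, Pla2g3 and Tcf21 had a mean signal below −4, where the 2 dim spike-in RNAs differed between arrays. Hdc is in the mast cell list, and Alox5ap and Cd53 are in the leukocyte list.

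Mast cell and leukocyte transcripts were abundant on both arrays labelled 0 h, although the samples are named as fibroblasts. Cpa3 read 6.19 and 6.25 on WT 0 h and KO 0 h, Il1rl1 5.89 and 6.28, Fcer1a 5.48 and 5.59, and Srgn 5.46 and 6.15. Of the 23 mast cell markers 14 were still well above background on each 24 h array, and 11 genes stand in more than 1 list. The protocols' adherence step or CD117 beads would remove mast cells if applied to these samples.

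Regulation within 1 cell population held at both times is argued against by the 2 Y-linked genes above a signal of −4 at 0 h, a limit chosen afterwards. Ddx3y was at least 21.3-fold (WT) and 78.0-fold (KO) lower at 24 h, and Eif2s3y at least 66.1-fold and 234-fold, so the 0 h samples held RNA that the 24 h samples largely did not. Of the 2 others, Kdm5d was well above background on no array, and Uty, close to the floor, was not lower at 24 h in WT (−6.59 at 0 h, −5.92 at 24 h). Mast cell RNA in the samples labelled 0 h may account for this. RNA of 1 kind of cell keeps its transcripts in 1 ratio, and 85.7% of the 42 measured mast cell and leukocyte markers lay within 0.5 of their median KO minus WT difference of 1.01, against 65.6% of 16614 other genes. The 9 brightest markers had a lower median, 0.53, with Cpa3 at 0.057 and Fcer1a at 0.10. The brightest spike-in RNAs read 7.06, 6.12, 4.51 and 3.78 on WT 0 h and 7.21, 6.37, 4.43 and 3.87 on KO 0 h. Those next in brightness differed more, at 2.17 and 0.17 on WT 0 h and 2.56 and 0.68 on KO 0 h. Whether a smaller difference of bright spots lowered the markers' median was not tested. Whether the time labels were exchanged in both genotypes cannot be told apart from labels that are right, because exchanging them leaves the size of the KO median (−6.87) and turns only its sign.

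More genes were lower than higher on KO 24 h against WT 24 h (2122 and 998). An offset of dim spots may account for much of it: the 2 spike-in RNAs with a mean below −4, added in equal amounts, were lower by a median of −0.75, while the 8 brighter ones had a median of 0.54. Of the 2, 1 read −6.29 on WT 24 h and −6.99 on KO 24 h. Both readings lay under those arrays' lowest signals well above background (−6.16 and −6.69). The offset thus rests mainly on the other, which read −4.34 and −5.14. Among 3485 dim genes 1216 were lower and 129 higher (90.4% of calls lower), with a median of −0.64. Lower expression over the whole brightness range in the KO clone, the biological explanation, was left open. Of calls among brighter genes 51.0% were lower (906 lower, 869 higher). Each array, however, was scaled to its own 75th percentile, which absorbs such a shift. The spike-ins did not enter that percentile. The 8 brighter ones ranged from 0.059 to 0.81, against a median of −0.011 for the brighter genes. Relative to these spike-ins gene signal was lower, which goes with that explanation. With 1 array per group it cannot be told apart from a difference in labelling.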

How the results depend on the processing

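The alternatives were set before the data were examined, except fibroblast gene scaling and leaving out genes lower at 24 h in both genotypes, which were chosen after seeing the data. No paired analysis was possible because each group has 1 sample and the labels give no replicate numbers that pair samples. A fit of genotype and time without their interaction, whose error is the difference of changes, was not run. With 1 array per group arrays were not left out in turn, and slide was not run as a block because all arrays lay on 1 slide. Causes were not tested unless given.

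Of the 68 lists that stood apart over the 5 differences, 64 did so with quantile normalization, 61 with normexp, 60 with the mean of probes, 58 with no filter and 57 with the stricter filter. The authors' table and fibroblast scaling shift all genes of a difference alike up to rounding and test no list. Of 551 values of named genes, 167 moved by over 1 SE and 3 turned sign with quantile normalization, 326 and 4 with normexp, and 49 and 3 with the mean of probes. With normexp KO minus WT at 0 h was 2.10 for Chst10, 2.45 for Tspan18 and 7.95 for Thy1. The filters leave a gene's own value as it is, so they test no single gene. Counts with the mean of probes stayed within 1.5 times those reported. The authors' table and the 2 SE rule hardly bear on counts, since nearly all 2-fold differences exceed 2 SE.

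Values that moved most follow as higher then lower. With quantile normalization, 1396 genes were lower in KO at 24 h, and the difference of changes had 1261 and 1510. The difference of changes in Acan (0.15), Plin1 (0.23) and Lpar5 (0.11) turned positive, each a dim gene. With normexp and quantile normalization together, 461 were higher in the WT difference between times, 996 and 1191 in KO, 800 higher in KO at 0 h, 669 lower in KO at 24 h, and 467 and 661 in the difference of changes. The median of all genes in WT was then 0.12, against 0.19 with quantile normalization alone. The difference of changes turned positive in Tnc (0.011) and, as with quantile normalization alone, in Acan (0.083), Plin1 (0.17) and Lpar5 (0.059).

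With no filter, which adds dim genes by construction, the counts were 8813 and 2134 in WT, 5835 lower in KO, 3819 and 1384 for KO against WT at 0 h, 1649 and 7605 at 24 h, and 1485 and 10814 for the difference of changes. YAP targets in WT turned to 0.0063 and hyaluronan genes in the difference of changes to −0.092. With the stricter filter, which keeps 8573 genes, they were 249 and 282, 793 and 476, 185 and 288, 354 and 309, and 322 and 281 in the same order. Matrix proteases in WT turned to −0.24 and fatty acid genes in KO against WT at 0 h to −0.17. With the mean of probes Atp8b5 (0.47) and Itga6 (−0.048) turned in the KO difference between times and Lpar2 (−0.22) in the difference of changes, because their probes disagree.

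Fibroblast scaling lowers every 24 h minus 0 h difference by 0.46 in WT and 0.51 in KO, from 42 genes, and the list medians with them. It gave 1306 and 1992 in WT and 387 and 3749 in KO, a move that the constant shift fixes by construction. Leaving out genes lower at 24 h in both genotypes left 1130 higher in KO at 0 h, a fall partly fixed by construction because the choice used KO 0 h signal. Signal over background limits dim genes: 31268, 30761, 28934 and 26714 spots were well above it on WT 0 h, KO 0 h, WT 24 h and KO 24 h.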

Other observations

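Every test of an explanation in this part was chosen after the result was seen, and so were the genes and gene families named here.

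Il1rl1, which encodes the IL-33 receptor, was far higher on KO 24 h than on WT 24 h at each of its 3 probes: 7.24, 6.11 and at least 38.0-fold. The probes differed in their KO difference between 24 h and 0 h (0.46, −2.41 and −3.61). Igfbp5 was at least 685-fold (WT) and 2231-fold (KO) lower at 24 h, Il13 at least 69.0-fold and 174-fold, and Il4 at least 93.6-fold and 318-fold.

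Single genes noticed among the genotype differences were these. Xist was at least 223-fold (0 h) and 157-fold (24 h) higher in WT. Dlk1 was higher in KO at both of its probes, by 2.59 and 2.97 at 0 h and 2.88 and 3.19 at 24 h. The brightest of 3 Meg3 probes was higher in KO, at least 143-fold at 0 h and by 5.04 at 24 h. The others were at least 18.2-fold and 3.32-fold higher at 0 h and at 24 h 1 was at least 6.05-fold higher and 1 showed no KO excess (−6.50 against −6.36). Peg3 was at least 10.7-fold and 17.5-fold higher in WT at 1 probe and at least 1.32-fold and 2.76-fold at the other, and Foxa2 at least 101-fold and 145-fold higher in KO at 1 probe and at least 16.9-fold and 21.9-fold at the other.

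Families were not compared with random lists. Of Hox genes at 0 h, 6 of 24 measured were lower in KO and 1 higher (median −0.51). At 24 h 9 of 21 were lower and 2 higher (median −0.76). The medians at 0 h and 24 h were −0.61 and −0.47 by quantile normalization and −0.34 and −0.31 by normexp. Of the 13 with a mean signal of −4 or above, 5 were lower and 1 higher at 0 h (median −0.74). At 24 h 3 of these were lower and 2 higher (median −0.25). Hoxb9 (−3.16 at 0 h, −4.87 at 24 h) and Hoxc13 (−2.18, −1.81) were lower, and Hoxa7 (3.62, 3.76) was higher. Of Lce genes, of the skin's cornified envelope, 7 of 11 measured were higher in KO at 0 h and 0 lower (median 1.73), and 5 of 8 higher at 24 h and 1 lower (2.61). Their medians stayed positive with quantile normalization (1.71, 2.59) and normexp (1.13, 2.05). Akr1c genes at 24 h were lower in KO in 3 of 4 and higher in 1 (median −2.84, −2.64 by quantile normalization, −1.87 by normexp). At 0 h 2 of 5 were higher in KO and 1 lower (median 0.69, 0.78 by quantile normalization, 0.18 by normexp). Between 0 h and 24 h in KO, 2 of 4 were higher at 24 h and 2 lower. The lower ones were Akr1c12 (−8.97) and Akr1c13 (−8.58), in the same direction as the mast cell markers. Copies of the Lce and Akr1c families are alike in sequence, and binding of 1 copy's RNA to another's probe was not analysed here.

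The medians of SRF and TGF-beta targets stood above random lists in the KO clone at both times, though at 0 h 8 of 17 SRF targets and 4 of 17 TGF-beta targets passed 2-fold, with 1 TGF-beta target lower, and at 24 h 7 of 16 and 9 of 17. Mast cell RNA in the 0 h samples is argued against as the whole cause, since at 24 h, where mast cell transcripts were low, the SRF median was 0.92 against 0.88 at 0 h, and the TGF-beta median 1.20 against 0.49. A candidate explanation is loss of Lpar1. It cannot be told apart from other differences of the KO clone, because each genotype is 1 line and 80 genes stood at least 8-fold apart in 1 direction at both times.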
